A study of Phaseolus vulgaris with 6 samples.

How the data were processed

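RNA sequencing measured messenger RNA in 6 libraries of hair-like structures of the common bean genotype L88-57, in 3 groups of 2 libraries (AG and EPI from trichomes, BG from hooked hairs). Groups and replicate numbers came from the sample titles. Per the labels' protocols, RNA was extracted with the RNeasy mini plus kit and libraries were made with a SMARTER mRNA-Seq kit, and whether the kit kept strand is not given in the sources used here. Trimmomatic, HISAT2 and StringTie are named in the submitters' processing notes, without versions. The genome build is not given in the sources used here. The gene IDs of the files end in v2.1, and coordinates are printed as the files give them.

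Each library's table gave, per the file headers, the coverage, FPKM and TPM of the same genes in all 6 libraries. The deposited TPM values are the authors' normalization for gene length and library size, and they summed to 920150 (BG library 1) to 961603 (EPI library 1) over the listed genes, so 3.84% to 7.98% of the TPM of a library lay outside the listed genes. The FPKM values deposited by the authors were a constant multiple of TPM within each library and were used as an alternative. The deposited coverage was used only for depth. The median ratio of coverage to FPKM rises with the number of mapped reads, and relative to EPI library 2 it was 1.128 and 1.273 in the AG libraries, 1.473 and 1.184 in the BG libraries and 1.206 in EPI library 1, on the assumption of equal read length. Whole reads could not be recovered: among 666 genes of low coverage whose coverage times span was a whole number of bases within 0.02, 2.55% of the values were multiples of 150 bases within 0.01 of a multiple. The planned count tests were therefore not run, the number of mapped reads per library was not determined, and no counting intervals are given.

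The files name no gene by symbol or product, and 0 of their gene IDs occur among the 34165 rows of the reference gene table (assembly P. vulgaris v2.0). The 30 gene lists fixed before the data were examined, which were to be matched on product names, could not be tested, and no list test or list of cell type markers was run. By the rule fixed before the data were examined, 2 gene IDs per direction are named in each comparison: those with the largest change among genes past the threshold whose 2 groups of libraries do not overlap, with a mean of at least 10 TPM on the higher side. Where none passed, the genes with the smallest p under the same conditions are given. Neighbouring-gene runs, the most abundant genes and the genes listed at 0 in one group were examined after the data were seen.

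Values were analysed as log2(TPM + 1) in limma 3.58.1 (R 4.3.3), over the 21571 genes with at least 1 TPM in at least 2 of the 6 libraries. A pseudocount of 1 understates the change of genes with low values. A mean was fitted per group over all 6 libraries, which left 3 residual degrees of freedom, and variances were moderated with a trend on mean expression (prior degrees of freedom 3.37). The 4 comparisons were BG against the mean of AG and EPI, BG against AG, BG against EPI and EPI against AG, two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. Comparisons that share libraries are not independent. With 2 libraries against 2, an exact two-sided permutation test of a single gene cannot go below p = 0.33, so single genes rest on the moderated variance of limma. SD values are between the 2 libraries of a group.

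Simulated data had the real means of 21571 genes, 200 changed genes drawn from the better expressed ones, and noise independent between genes. The fit was tested on such data in 10 draws. For BG against both trichome groups it recovered 36.7% of 4-fold and 89.2% of 16-fold changes with a mean of 6.7 false calls, and for EPI against AG 18.2% and 80.3% with 4.5 false calls. Among recovered genes 0 had the wrong direction. Changes of 2-fold were recovered in 1.19% and 0.299% of cases.

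Runs were sets of at least 3 tested genes, consecutive by start position on a chromosome or scaffold, called in the same direction in BG against both trichome groups. Gene calls were shuffled 1000 times over the same positions. Genes that overlap on either strand, or that have near-identical copies, may share reads.

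Alternatives were another pseudocount, no filter or a stricter filter, median-of-ratios or quantile scaling, FPKM, no variance trend, a replicate block, a fold threshold, the groups compared alone, and each library left out in turn. The median log2 change over all genes was 0.184 for BG against AG and 0.151 for EPI against AG as deposited, and 0.037 and 0.008 after median-of-ratios scaling, in which AG library 1 had a size factor of 0.832. Figures were drawn with matplotlib 3.10.9.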

Results

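RNA of hair-like structures was sequenced in the common bean (Phaseolus vulgaris) genotype L88-57, grown in normal conditions. Trichomes are hair-like outgrowths of the plant epidermis, and hooked hairs are hairs with a curved tip. The 6 libraries fell into 3 groups of 2. The labels call AG and EPI trichomes, and BG is the group of hooked hairs. They do not spell out these codes, so what else differs between the groups, such as organ or position on the plant, is unknown. Each library listed TPM values for the same genes, identified by Phvul numbers. Between 19194 (AG library 1) and 20556 (BG library 1) genes reached 1 TPM, 17418 genes reached it in all 6 libraries, and 2012 genes were listed at 0 in all 6. Raw read totals were not used here, but the ratio of coverage to FPKM placed the libraries within 1.473-fold of each other in depth if read lengths were equal, with BG library 1 the deepest and EPI library 2 the shallowest. The labels do not say whether the 2 libraries of a group came from separate plants, so the p-values measure the spread between these libraries, which may be technical.

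By group mean, a different gene had the highest level in each of the 3 groups. In AG it was Phvul.008G271700.v2.1 (chromosome 8, 61570709 to 61571513), at 21006 ± 10158 TPM (SD, n = 2), against 2115 ± 1026 TPM in EPI and 1455 ± 657 TPM in BG. Its level was lower in BG than in AG by limma (log2 change -3.84, adjusted p = 0.0394), while the difference between EPI and AG did not pass (log2 change -3.31 ± 0.81 SE, adjusted p = 0.179). In BG the gene with the highest mean was Phvul.003G109100.v2.1 (chromosome 3, 27561953 to 27562969), at 4478 ± 798 TPM. In BG library 2 alone, Phvul.004G075100.v2.1 stood higher, at 4807 TPM. Phvul.003G109100.v2.1 stood at 3358 TPM in EPI library 1 and 97.2 TPM in EPI library 2, and its difference between hooked hairs and trichomes did not pass (log2 change 3.62 ± 1.30 SE, adjusted p = 0.140). In EPI the leading gene was Phvul.005G027300.v2.1 (chromosome 5, 2539594 to 2540118), at 6493 ± 1316 TPM, with 8398 ± 654 TPM in AG. The 10 most abundant genes held 8.69% and 6.16% of the listed TPM in the AG libraries, 3.99% and 3.98% in the EPI libraries, and 3.89% and 3.02% in the BG libraries. These 4 genes were chosen after their values were seen.

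Across the 21571 genes tested, replicate libraries correlated at Pearson r = 0.923 (AG), 0.930 (BG) and 0.903 (EPI) on the log2 scale, a description across genes, which are not independent replicates. BG and AG libraries correlated at 0.739 to 0.793. EPI library 1 lay nearer to the hooked hairs than EPI library 2 did, with r = 0.847 and 0.830 to the 2 BG libraries, against 0.757 and 0.782. On the first principal component, which held 53.0% of the variance, EPI library 1 sat at -0.7, the other trichome libraries between -89.3 and -59.5, and the BG libraries at 102.2 and 108.1.

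**Figure D1:**
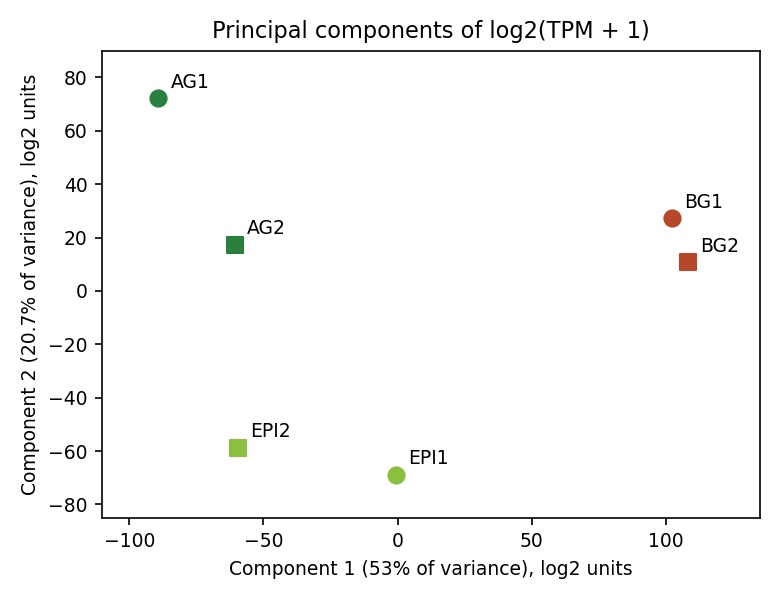
Principal components of log2(TPM + 1) over 21571 genes, with component 1 (53.0% of the variance) on the x axis and component 2 (20.7%) on the y axis, in log2 units. Each point is a library, circles are replicate 1 and squares replicate 2. The BG libraries lie at 102.2 and 108.1 on component 1, and EPI library 1 at -0.7 lies between them and the other 3 trichome libraries.

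The central question of the series was how hooked hairs differ from trichomes. Against the mean of the AG and EPI groups, 713 genes were higher and 1161 lower in hooked hairs, together 1874 genes or 8.69% of those tested (limma, Benjamini-Hochberg adjusted p under 0.05). Among them, 479 were at least 4-fold higher and 698 at least 4-fold lower on the log2(TPM + 1) scale, and 62 and 71 passed 16-fold. Both BG libraries lay outside the range of all 4 trichome libraries, in the direction of the change, for 1851 of the 1874 genes. Over all tested genes, 31.5% had such separated groups, where chance gives 13.3%. Called genes were spread over all 11 chromosomes, from 7.98% of the tested genes on chromosome 2 to 9.90% on chromosome 5. Presence in a single kind of structure was rare under a strict rule, which a trace level in any library of the other kind breaks. A set of 12 genes reached 1 TPM in both BG libraries and was listed at 0 in all 4 trichome libraries, and 8 genes showed the opposite pattern.

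The largest rise in hooked hairs was in Phvul.009G108100.v2.1 (chromosome 9, 16762151 to 16763330), which stood at 1677 ± 783 TPM in BG, 59.4 ± 71.9 TPM in AG and 3.69 ± 3.32 TPM in EPI (SD, n = 2; log2 change 7.10 ± 0.99 SE, adjusted p = 0.013). It was followed by Phvul.009G252900.v2.1 (chromosome 9, 37324930 to 37326730), with 413.9 ± 43.7 TPM in BG against 4.78 ± 6.15 TPM in AG and 16.8 ± 22.5 TPM in EPI (log2 change 6.24 ± 1.25, adjusted p = 0.0332). The largest fall was in Phvul.006G033900.v2.1 (chromosome 6, 12767922 to 12769746), from 210.7 ± 9.0 TPM in AG and 450.2 ± 413.2 TPM in EPI to 2.90 ± 1.39 TPM in BG (log2 change -6.16 ± 0.60, adjusted p = 0.00851). Next was Phvul.001G168900.v2.1 (chromosome 1, 42533314 to 42534170), which fell from 789 ± 46.8 TPM in AG and 1557 ± 1152 TPM in EPI to 14.98 ± 3.83 TPM in BG (log2 change -6.02 ± 0.47, adjusted p = 0.00851). The count of called genes rested on both BG libraries: it was 234 (36 higher, 198 lower) without BG replicate 1 and 0 without BG replicate 2, and it was 1081 without AG replicate 1 and 1046 without the filter on low values. Without BG replicate 1, Phvul.009G108100.v2.1, Phvul.009G252900.v2.1 and Phvul.006G033900.v2.1 did not pass (log2 change 7.60, 6.35 and -5.79). Phvul.009G252900.v2.1 also lost its call without AG replicate 2 (log2 change 5.54), without the filter on low values (6.24) and with a pseudocount of 0.1 (6.89). Without EPI replicate 1, the trichome library nearest to the hooked hairs, the count of called genes was higher than with all 6 libraries.

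**Figure D2:**
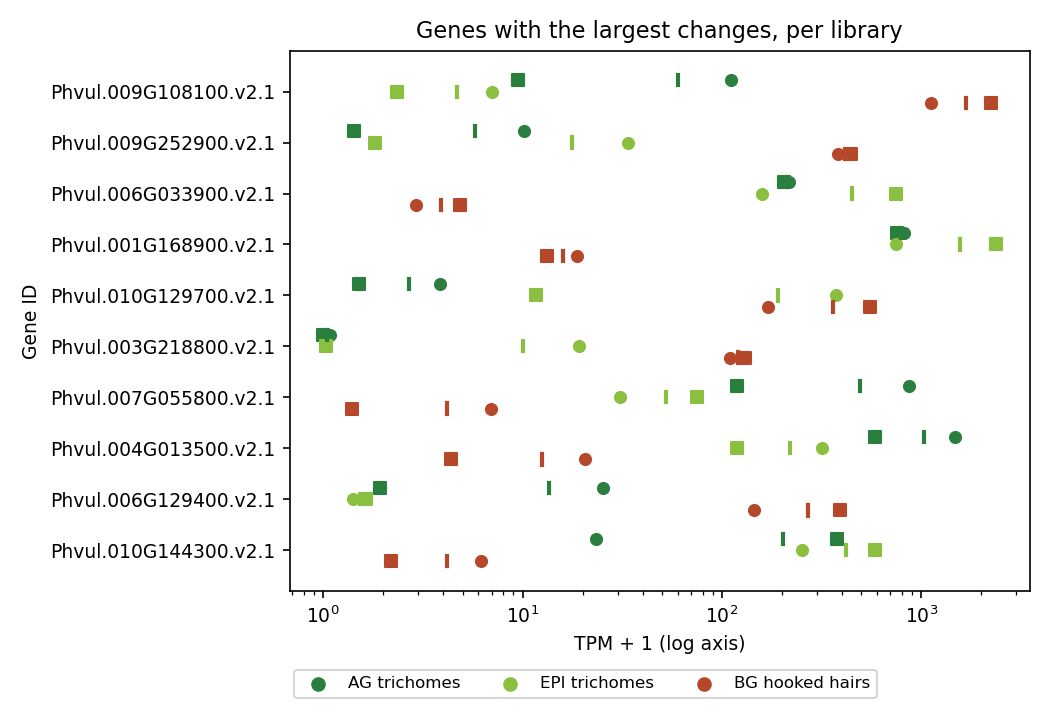
TPM + 1 on a log axis for the 10 genes with the largest changes in the 3 comparisons with hooked hairs. Circles are replicate 1, squares replicate 2 and vertical ticks the mean of the 2 libraries of a group. The 2 BG values of Phvul.009G108100.v2.1, at 1123 and 2231 TPM, lie above its highest trichome value of 110.2 TPM.

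Genes that changed lay next to each other more often than shuffled gene orders gave. Of the 1874 called genes, 59 lay in 18 runs of at least 3 neighbouring tested genes called in the same direction. The 1000 shuffles gave a mean of 3.96 runs and a highest value of 13 (permutation p = 0.001, the smallest that these shuffles can give). Shuffling treats each call as a separate event, which genes that share reads break. Runs of genes that may share reads, such as those on chromosome 4 described below, were not left out. Runs of lower genes numbered 12, with 40 genes, and runs of higher genes numbered 6, with 19 genes. The number of runs was 40 without EPI replicate 1, 12 without EPI replicate 2, 11 and 10 without AG replicates 1 and 2, 2 without BG replicate 1 and 0 without BG replicate 2. It was 4 without the filter on low values and 11 with a pseudocount of 10. The number of runs did not follow the number of called genes alone. With a stricter filter of at least 5 TPM in 2 libraries, 1671 called genes gave 19 runs, against 18 from 1874 genes. These alternatives were not shuffled. They therefore do not show whether neighbours clustered beyond chance in each setting.

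The run with the highest summed level in trichomes lay on chromosome 4. There, 3 runs between 9431905 and 23321146 held 12 short genes of 751 to 1518 bp, all lower in hooked hairs by a log2 change of -4.87 to -4.42 (largest adjusted p = 0.0116). Summed over the 12 genes, the level was 18444 ± 10111 TPM in AG, 9857 ± 4223 TPM in EPI and 573 ± 313 TPM in BG (SD, n = 2). AG was thus 32.2-fold and EPI 17.2-fold above BG. Leaving out one library at a time gave folds of 19.7 (without AG replicate 1) to 52.4 (without BG replicate 1) for AG and 12 (without EPI replicate 1) to 28 (without BG replicate 1) for EPI. The 12 genes held 2.72% and 1.20% of the listed TPM in the AG libraries, 1.34% and 0.717% in the EPI libraries, and 0.0864% and 0.0369% in the BG libraries. The runs spanned 9431905 to 9502854 with 3 genes, 22281504 to 22508255 with 4 genes and 23117065 to 23321146 with 5 genes. Over the whole interval of 13.9 Mb, 201 genes were tested, 17 were called lower and 5 higher. The call held for 9 of the 12 genes without BG replicate 1 and for 0 of them without BG replicate 2 (largest adjusted p = 0.0564 and 0.119), with a median log2 change of -5.14 and -3.81. Copies of similar sequence were not distinguished here, so the split of reads between these 12 genes is uncertain.

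**Figure D3:**
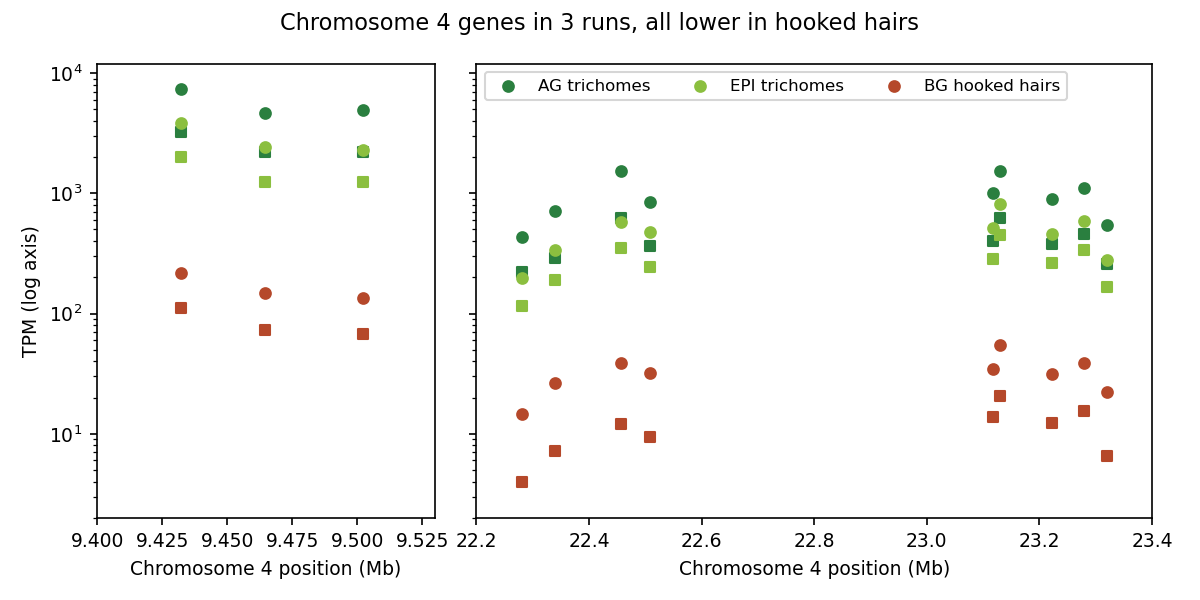
TPM on a log axis against the position on chromosome 4 (Mb) for the 12 genes of 3 runs, in all 6 libraries, with circles for replicate 1 and squares for replicate 2. In each gene both BG values lie below all 4 trichome values, with a log2 change of -4.87 to -4.42.

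Other runs lower in hooked hairs lay on chromosomes 6 and 7. On chromosome 6, 3 genes between 30914793 and 30924651 summed to 1752 ± 940 TPM in AG, 1314 ± 349 TPM in EPI and 132.1 ± 81.96 TPM in BG. On chromosome 7, the 3 genes between 4645046 and 4667007 stood at 1893 ± 822 TPM in AG, 1189 ± 43.5 TPM in EPI and 177.7 ± 28.8 TPM in BG. A further 4 genes on chromosome 4, between 43739624 and 43786112, reached 229 ± 33.9 TPM in AG, 107.9 ± 35.0 TPM in EPI and 31.6 ± 2.47 TPM in BG. Among runs higher in hooked hairs, 3 genes on chromosome 11 between 44057980 and 44104775 summed to 324.6 ± 52.6 TPM in BG, 12.3 ± 6.07 TPM in AG and 42.5 ± 41.7 TPM in EPI. On chromosome 1, 3 genes between 19833436 and 20018800 summed to 375.6 ± 216.7 TPM in BG against 14.2 ± 7.69 TPM in AG and 22.6 ± 26.8 TPM in EPI. On chromosome 10, 4 genes between 2485323 and 2520814 summed to 278.7 ± 7.12 TPM in BG, 78.9 ± 3.20 TPM in AG and 71.5 ± 35.8 TPM in EPI.

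Hooked hairs were next compared with each trichome group alone. Against AG, 753 genes were higher and 1152 lower in BG, 1905 in all (limma, adjusted p under 0.05), with 519 and 808 of them at least 4-fold apart. The largest rises were in Phvul.010G129700.v2.1 (chromosome 10, 41082223 to 41083071), from 1.69 ± 1.65 to 361.8 ± 272.1 TPM (log2 change 6.99 ± 1.54 SE, adjusted p = 0.0441), and in Phvul.003G218800.v2.1 (chromosome 3, 44740686 to 44741628). The latter stood at 119.7 ± 14.5 TPM in BG, at 0.08 TPM in AG library 1 and listed at 0 in AG library 2 (log2 change 6.86 ± 1.22, adjusted p = 0.0275). The largest falls were in Phvul.007G055800.v2.1 (chromosome 7, 4657074 to 4663363), from 493 ± 531 TPM in AG to 3.17 ± 3.93 TPM in BG (log2 change -6.69 ± 1.12, adjusted p = 0.0239), and in Phvul.004G013500.v2.1 (chromosome 4, 1530649 to 1538171), from 1030 ± 632 to 11.5 ± 11.5 TPM (log2 change -6.61 ± 0.86, adjusted p = 0.0169). Phvul.007G055800.v2.1 is a member of the chromosome 7 run. Phvul.010G129700.v2.1 stood at 371.2 TPM in EPI library 1 and 10.7 TPM in EPI library 2, and it did not pass the threshold with a pseudocount of 10 (log2 change 4.77), after median-of-ratios or quantile scaling (6.83 and 6.68), on FPKM values (6.51) or without the variance trend (6.99). Without the filter on low values, 556 genes were called, and the 2 named rises and Phvul.007G055800.v2.1 did not pass, at the log2 changes given. The count of called genes was 0 without BG replicate 1, BG replicate 2 or AG replicate 1, and 1054 without AG replicate 2, where the 2 named rises did not pass (log2 change 6.32 and 6.80).

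Against EPI, 359 genes were higher and 717 lower in BG, 1076 in all, of which 305 and 562 were at least 4-fold apart. Phvul.009G108100.v2.1 again showed the largest rise, with a log2 change of 8.61 ± 1.14 SE (limma adjusted p = 0.0206). Phvul.006G129400.v2.1 (chromosome 6, 23721882 to 23724151) rose from 0.523 ± 0.162 TPM in EPI to 267.9 ± 175.5 TPM in BG (SD, n = 2; log2 change 7.29 ± 1.15, adjusted p = 0.0259). The largest fall was in Phvul.010G144300.v2.1 (chromosome 10, 42602084 to 42603658), from 419 ± 238 TPM in EPI to 3.17 ± 2.81 TPM in BG (log2 change -6.71 ± 1.27, adjusted p = 0.0389), and Phvul.006G033900.v2.1 followed with a log2 change of -6.51 ± 0.69 (adjusted p = 0.0181). The count was 0 without either BG library, 8 without EPI replicate 2 and 933 without EPI replicate 1. Phvul.010G144300.v2.1 did not pass without EPI replicate 1 (log2 change -7.33), without EPI replicate 2 (-6.10) or with a pseudocount of 10 (-4.92), and the 2 named rises did not pass without EPI replicate 2 (7.81 and 7.40). Without the filter on low values, 301 genes were called, and these 3 genes did not pass, at the log2 changes given. Whether a gene's difference from BG was larger in AG or in EPI is tested by the comparison of EPI with AG.

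Between the trichome groups no gene passed the threshold. The smallest adjusted p of EPI against AG was 0.168 by limma, with 3554 of 21571 genes under an unadjusted p of 0.05, where 1079 are expected by chance. Without EPI replicate 2, where EPI was library 1 alone, some genes passed. That library lay nearest to the hooked hairs among the trichome libraries, so these genes may reflect that library and not the group. The genes with the smallest p and separated libraries had large differences. Phvul.008G180500.v2.1 (chromosome 8, 51021869 to 51023764) stood at 46.9 ± 17.0 TPM in EPI, 0.278 ± 0.093 TPM in AG and 0.466 ± 0.450 TPM in BG (log2 difference 5.18 ± 0.45 SE), and Phvul.003G082300.v2.1 (chromosome 3, 13663735 to 13665489) at 62.1 ± 26.8 TPM in EPI and 4.97 ± 0.24 TPM in AG (log2 difference 3.33 ± 0.34). The neighbouring genes Phvul.007G009200.v2.1 and Phvul.007G009100.v2.1 (chromosome 7, 661883 to 663334 and 657680 to 659317) had log2 differences of -2.77 ± 0.28 and -2.59 ± 0.27, with 450.1 ± 35.7 and 110.9 ± 10.4 TPM in AG against 66.6 ± 21.0 and 17.9 ± 5.34 TPM in EPI. All 4 had an adjusted p of 0.168. A set of 9 genes reached 1 TPM in both EPI libraries and was listed at 0 in both AG libraries. The opposite held for 1 gene, Phvul.003G098600.v2.1 (chromosome 3, 25374507 to 25375326), at 1.53 and 1.11 TPM in AG, named after its values were seen. On simulated data with 200 changed genes, drawn from the better expressed of the 21571, the fit recovered 18.2% of 4-fold and 80.3% of 16-fold changes between EPI and AG. Recovery depends on the share of genes that change, which is unknown here, so these values do not give the reach in the real data.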

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

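The tests of admixture and of depth were chosen after the results were seen. Each of 19 values was examined for a library far from the other 3 among the 4 trichome libraries, and 4 stood out by Dixon's criterion. The criterion assumes 4 like libraries, while these come from the AG and EPI groups. Most of the values also belong to genes picked for their differences in these data. Its nominal rate of about 1 in 20 therefore does not apply here. Phvul.003G218800.v2.1 stood at 18.1 TPM in EPI library 1 and at no more than 0.08 TPM in the other 3 (gap over range 0.974). Phvul.001G168900.v2.1 stood at 2372 TPM in EPI library 2, against 743 to 822 TPM (0.913). Phvul.006G129400.v2.1 stood at 24.4 TPM in AG library 1 and at no more than 0.93 TPM elsewhere (0.891). The number of genes at 1 TPM or more was 19194 in AG library 1, against 20135 to 20276 (0.870).

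EPI library 1 lay between the other trichome libraries and the hooked hairs. For the 753 genes higher in BG than in AG, it stood at a median of 40.2% of the way from AG to BG, against 20.9% for EPI library 2. For the 1152 lower genes the values were 20.6% and 20%. These genes were picked for their difference between the same AG and BG libraries. Chance error in those means therefore places any EPI library part of the way, and only the contrast between the EPI libraries is free of this. Admixture of BG-like RNA at a single share, as the whole cause, was examined over 59 genes. They had at least 50 TPM in both BG libraries and at least 8-fold less in the other 3 trichome libraries. The median share needed was 27.4%, with quartiles of 5.1% and 60.5%. Of these genes, 25.4% lay under 25% of the level the median implies, and 6 lay above the BG mean. The 95% exact binomial interval of the 25.4%, 15% to 38.4%, treats genes of a single library as independent, which they are not. Only 1 of the 59 differed over 4-fold between the BG libraries, but requiring 50 TPM in both holds this count down. As a description, without a valid test, the uneven shares argue against a single share for these genes. Depth stays open: in both trichome groups the deeper library lay nearer to the hooked hairs on the first component (EPI library 1 at 1.206 times the depth of EPI library 2, AG library 2 at 1.273 times against 1.128 for AG library 1), while AG library 2 was deeper than EPI library 1 and lay at -60.7 against -0.7, and BG library 1, the deepest, lay at 102.2 against 108.1 for BG library 2. Over 1776 genes with a mean of at least 100 TPM, EPI library 1 stood at 30.4% of the way from the mean of the other 3 trichome libraries to BG, past these 3 (-14.8% to 9.1%) but by less than their range. A difference between the plants or the tissue collected for the 2 EPI libraries also stays open, untested.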

How the results depend on the processing

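The alternatives for runs of neighbouring genes were chosen after seeing the data. Leaving out the filter on low values lowered the counts of called genes to 1046 for hooked hairs against both trichome groups, 556 against AG and 301 against EPI, with more genes tested (25421). Leaving out one library at a time gave 0 to 2455 genes for both trichome groups together, 0 to 2430 against AG, 0 to 961 against EPI and 0 to 14 for EPI against AG. The 0 values arose without BG replicate 1 (BG against AG and against EPI), without BG replicate 2 (all 3 comparisons with BG) and without AG replicate 1 (BG against AG), where the remaining library of a group was assumed to vary like the others. The 14 genes between EPI and AG arose without EPI replicate 2, and every other alternative gave 0. Under the other pseudocounts, stricter filter, scalings, FPKM, variance and fold alternatives the 3 counts with BG stayed within 1.5 times, and no gene called in both fits changed direction. Differences between replicates 1 and 2 correlated at 0.096 (AG with BG), -0.032 (AG with EPI) and 0.245 (BG with EPI). An effect shared by libraries of the same replicate number therefore stays open. A replicate block gave 1601, 1438, 855 and 0 genes. It ended the calls of Phvul.010G129700.v2.1 (BG against AG, log2 change 6.99), Phvul.006G129400.v2.1 and Phvul.010G144300.v2.1 (BG against EPI, 7.29 and -6.71). Of 200 values of the called named genes under the alternatives, 149 kept their call, 51 lost it and 0 reversed. Of the genes called between hooked hairs and both trichome groups, 38.0% were higher as deposited, 33.6% and 34.3% after median-of-ratios and quantile scaling, 29.9% with a pseudocount of 0.1, 46.7% without EPI replicate 1 and 15.4% without BG replicate 1. Runs of neighbouring genes numbered 4 without the filter and 11 with a pseudocount of 10, against 18, with no shuffles run for these alternatives. In simulated data with 2 libraries per group, 1.19% of 2-fold differences were recovered for hooked hairs against trichomes. The recovery in the real data, with another share of changed genes, may differ.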

Other observations

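All tests in this part were chosen after the results were seen. Further runs of neighbouring genes separated hooked hairs from trichomes. On chromosome 11, 3 genes between 50239048 and 50263331 summed to 64.0 ± 21.5 TPM in BG and 1.73 ± 2.44 TPM in AG (SD, n = 2), and they were listed at 0 in both EPI libraries. Of these, 1 neighbouring pair overlaps, which leaves the split of reads between them uncertain. On scaffold_84, 3 genes between 14329 and 89747 summed to 612.9 ± 176.7 TPM in BG, 112.3 ± 54.8 TPM in AG and 84.2 ± 5.18 TPM in EPI. On chromosome 9, the 3 genes between 34097637 and 34175171 stood at 499.7 ± 50.7 TPM in BG, 130.3 ± 35.5 TPM in AG and 261.4 ± 70.9 TPM in EPI. Lower in hooked hairs were 3 genes on chromosome 10 between 5753580 and 5808058, with 3.69 ± 1.31 TPM in BG, 25.8 ± 2.07 TPM in AG and 70.8 ± 18.9 TPM in EPI.

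The 12 chromosome 4 genes differed between replicates as well as between groups: their summed TPM in replicate 1 was 2.27 times that in replicate 2 in AG, 2.26 times in BG and 1.87 times in EPI. Beyond runs of called genes, the log2 changes of neighbouring genes correlated over all tested genes, which are not independent replicates. Neighbours that do not overlap gave r = 0.148 on the same strand (11208 pairs, rho = 0.123) and r = 0.077 on opposite strands (9947 pairs, rho = 0.071), and the highest of 1000 shuffles gave 0.033 and 0.030 (permutation p = 0.001 for both, the smallest they can give, Benjamini-Hochberg adjusted 0.0012 over 6 classes of neighbours). For neighbours over 20 kb apart on the same strand r was 0.150 (2472 pairs, rho = 0.104, permutation p = 0.001). On opposite strands it was 0.078 (2183 pairs, rho = 0.065, permutation p = 0.002, adjusted 0.002), where the highest shuffle gave 0.089. Both same-strand classes of separate neighbours held pairs of the 12 chromosome 4 genes, which may share reads and have log2 changes of -4.87 to -4.42. The correlations without these pairs were not computed. Overlapping genes on the same strand gave r = 0.644 (127 pairs, rho = 0.696), and on opposite strands r = 0.242 (196 pairs, rho = 0.215), with permutation p = 0.001 for both. Runs of called genes numbered 18, against at most 13 in the shuffled orders (permutation p = 0.001, the smallest they can give). Shuffling treats each call as a separate event. The 12 chromosome 4 genes, which made up 3 of the runs, may share reads, and some chromosome 11 runs held an overlapping pair. No shuffles were run without these, so random placement of separately measured genes was not tested.

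A hypothesis for the common fall of the 12 chromosome 4 genes is that they are near-identical copies whose reads were shared out between them. It predicts that they also share chance differences between replicates, and the SD over the 12 genes of the log2 difference between replicates, averaged over the 3 groups, was 0.16, below the lowest (0.32) of 10000 random lists of 12 among 216 other genes at least 4-fold lower in hooked hairs with at least 100 TPM in trichomes (median 0.76, permutation p = 1e-04, the smallest the draws can give). Shared reads would give this, and joint regulation of a gene array would predict it too. The 12 genes were picked for their like fall in these data, and the 216 others were not matched to them in level or position. In every group the summed TPM of the 12 was higher in replicate 1, so the shared differences need not be chance. The p-value therefore does not decide between these explanations. Overlap of the gene models is argued against, since 0 neighbouring pairs in the 3 runs overlap. If reads were shared, how many of the 12 genes changed is unknown, and sharing with copies outside the 12 was not tested.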
